A study of Mus musculus with 9 samples.

How the data were processed

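Sebaceous glands, hair follicles and interfollicular epidermis were dissected by hand from the tail epidermis of wild-type female mice, per the labels' protocols. Each sample pooled dissected pieces of one compartment, and 3 biological replicates per compartment gave 9 arrays. RNA was extracted with the RNeasy micro kit, amplified with the WT-Ovation Pico system and the Exon Module, and labelled with biotin, per the labels' protocols. The submitters' processing notes name RMA (robust multi-array average), Affymetrix Power Tools and the mouse genome build mm9, without versions, roles or order. The versions, and the filter that left these probe sets, are not given in the sources used here.

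The authors deposited an intensity for each probe set and array, on a linear scale from 2.5 to 30815 although RMA usually ends on a log2 scale. The deposited table held 154736 probe sets and 9 columns, one per array. The median of an array lay between 176 and 234, so the arrays had not been brought to one median. No detection calls were used, so the signal over background of a gene is unknown, and differences of dim genes may be compressed. The number of arrays limits the precision, with a median SE of 0.207 for a log2 difference.

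The log2 of each value was taken, with no pseudocount and no further normalization. Gene symbols came from the array's platform annotation, in which 146964 probe sets had 1 symbol, 1060 had several and 6712 had none. Only those with 1 symbol were named. A gene's value was the median log2 value of its probe sets, which gave 14507 genes with a median of 8 probe sets each, and 911 genes rested on 1 probe set. Old symbols were updated through a table of RefSeq genes on assembly GRCm38 for 1754 genes, and 14472 genes were found in it. That assembly differs from the build of the notes, so the table served for names alone and no coordinates are given.

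Groups followed the sample titles, source names and tissue characteristics. The array file name in each description named another compartment for 9 of 9 arrays. Lists of marker genes were therefore set against the titles with an exact two-sided permutation test over the 84 splits of 9 arrays into 3 and 6. The labels give no batch.

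limma 3.58.1 in R 4.3.3 was fitted to all 9 arrays with one mean per compartment, followed by eBayes, for 3 comparisons that share the fit. P-values were adjusted by Benjamini-Hochberg over the 14507 genes. A gene counted as changed at an adjusted p under 0.05 and an absolute log2 difference of at least 1. A signature gene passed that threshold upward against both other compartments. Gene lists were tested with limma's camera, which sets a list against other genes, at a preset correlation of 0.01, adjusted over 114 pairs of list and comparison. The test was repeated with an estimated correlation. They were also tested with fry, which asks another question: whether a list changed in one direction, without reference to other genes. Each SE of a gene is that of the limma fit.

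The design, the thresholds, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, apart from those named as chosen later. The rule named, per comparison, the 6 largest rises and 6 largest falls among changed genes whose groups did not overlap. It further named, for each list described, up to 4 members with the smallest p and up to 2 of the opposite direction, and for each signature the 8 genes with the largest smaller difference. Gene models without an official name and olfactory or immunoglobulin genes were counted without being named.

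The code was tested on simulated data for SG against IFE over 14507 genes. Of 100 genes changed by a log2 difference of 1.5 it recovered 86, and of 100 changed by 3 it recovered 98, with 4 false calls. With no simulated change it made 0 calls over the 3 comparisons, and 3 of 100 lists without change passed an unadjusted camera p of 0.05. The genes were simulated independently of each other, so this does not cover lists whose genes move together. In the real data the estimated correlation reached 0.914, for the hair shaft and inner root sheath list.

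The alternatives were the replicate number or a letter in the array names as a block, quantile normalization, median centring, leaving out dim genes, the brightest probe set of each gene, eBayes with trend and robust, array weights, a fit of only the groups compared, other log2 thresholds and leaving out each array. Leaving out SG replicate 3 and HF replicate 2 together was added after the data were seen.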

Results

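The skin of the mouse tail carries hair follicles, each with sebaceous glands attached, set in an interfollicular epidermis that is organised into scale and interscale regions. The study asked which genes are typical of each of these epidermal compartments. Sebaceous gland (SG), hair follicle (HF) and interfollicular epidermis (IFE) were dissected by hand from the tail epidermis of adult wild-type females of a mixed C57BL6/CBA background, matched for age and sex. The RNA of pooled pieces was amplified and hybridised to a mouse exon array, with 3 biological replicates per compartment and 9 arrays in all. A sebaceous gland is built of sebocytes, which fill with lipid and burst. The hair follicle makes the hair shaft and the sheaths around it, and the interfollicular epidermis makes the cornified barrier of the skin surface. Expression was compared for 14507 genes, each measured by a median of 8 probe sets (an exon-level unit of the array). The median deposited signal ran from 176 on SG replicate 1 to 234 on IFE replicate 3. P-values here measure the spread between pooled dissections that were labelled biological replicates, and the small number of arrays limits their precision.

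Arrays of one compartment resembled each other more than arrays of different ones in most cases. The correlation across genes of log2 signal was 0.921 to 0.977 within a compartment and 0.846 to 0.93 between compartments, where genes are not independent replicates. The first principal component carried 41.8% of the variance and separated IFE from the other compartments. The second carried 27.2% and separated SG from HF. SG replicate 3 stood apart from SG replicates 1 and 2 on the second component, at 8.30 against 37.8 and 35.2, and its correlation with HF replicate 2, 0.93, exceeded the 0.921 it had with SG replicate 1. Among the 14507 genes, 3548 (24.5%) differed among the compartments in limma's moderated F test at a Benjamini-Hochberg adjusted p under 0.05. The count was 1360 with the last letter of the array names as a block (the letter block), 5890 with array weights and 2305 without IFE replicate 2. SG replicate 1, HF replicate 1 and IFE replicate 3 shared a letter with no other array, so that block compared the compartments on the remaining arrays. Deviations of same-letter arrays from their group means correlated at -0.13 to 0.11.

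**Figure D1:**
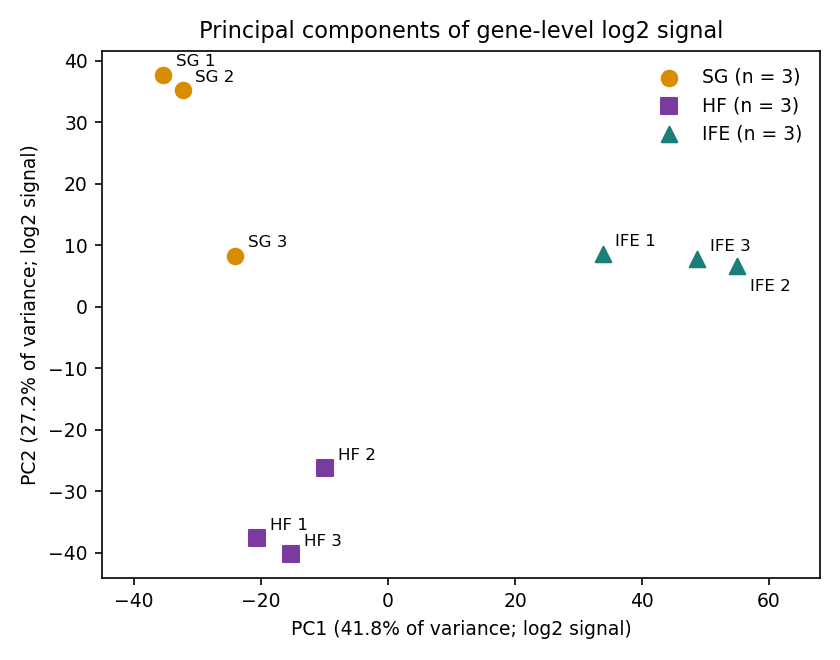
Scores of the 9 arrays on the first 2 principal components of gene-level log2 signal, with SG as circles, HF as squares and IFE as triangles. PC1 (41.8% of variance) places the IFE arrays to the right of the others, and SG replicate 3 lies at 8.30 on PC2, below SG replicates 1 and 2 at 37.8 and 35.2.

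The array file names given in the sample descriptions named another compartment than the titles did, for all 9 arrays, so groups were taken as titled. Marker genes fixed before the data were examined were set against both namings. The sebocyte list (14 genes measured) was higher in the arrays titled SG than in the other 6 by 2.38 on the log2 scale (exact two-sided permutation p = 0.0119, adjusted p = 0.0357 over 9 list and group pairs). The resting hair follicle list (14 genes) was higher in the arrays titled HF by 0.857 (exact permutation p = 0.0238, adjusted p = 0.0429). It mainly set the IFE apart, with group means of 0.571 in HF, 0.291 in SG and -0.862 in IFE. Between SG and HF alone it did not stand apart in camera (adjusted p = 0.174). The list of suprabasal IFE genes (12 genes) was higher in the arrays titled IFE by 0.975 (exact permutation p = 0.0119, adjusted p = 0.0357). With 84 splits of the arrays, 0.0119 was the smallest p the test could give. For each of the 3 lists, the 3 highest arrays were those of the titled compartment. Leaving out an HF or an IFE array raised the p of the resting hair follicle list to 0.143 or 0.125, while the HF arrays left in, 2 or 3, stayed the highest.

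**Figure D2:**
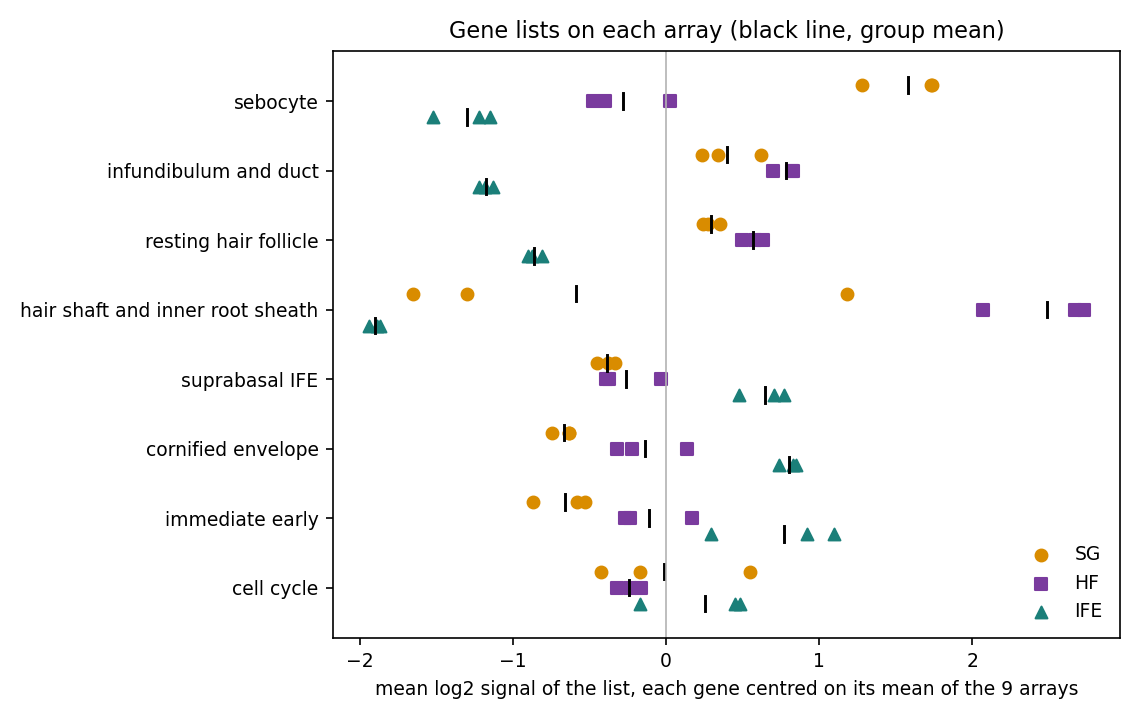
Mean log2 signal of 8 gene lists on each of the 9 arrays, each gene centred on its mean over the arrays (circles SG, squares HF, triangles IFE, black lines group means). The sebocyte list lies between 1.28 and 1.74 on the SG arrays and below 0.1 on the others, and SG replicate 3 lies at 1.18 on the hair shaft list, against -1.65 and -1.30 for SG replicates 1 and 2.

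Against the IFE, the SG was higher in 11 of 14 sebocyte genes and lower in 12 of 20 cornified envelope genes. Both lists stood apart in camera, and neither did with an estimated correlation (adjusted p = 0.137 and adjusted p = 0.131). The largest rise was in Far2, a fatty acyl-CoA reductase that supplies fatty alcohols for wax esters, which was 40.4-fold higher in SG (log2 difference 5.34 ± 0.29 SE, n = 3 per group, adjusted p = 1.18e-06). It was followed by the protease inhibitor Serpina3b (5.27), the fatty acid transporter Cd36 (5.17), the aldo-keto reductase Akr1c21, the fatty acid 2-hydroxylase Fa2h (4.87) and the monoglyceride lipase Mgll (4.74). The largest falls were in the protease inhibitor Serpinb13 (-4.08 ± 0.27, adjusted p = 4.37e-06), the adhesion protein Nectin3 (-3.88), Wfdc12 (-3.84), the interleukin 1 family member Il1f9 (-3.69), the late cornified envelope gene Lce1c (-3.61) and Serpinb7 (-3.51). In all, 1377 genes (9.49%) changed at an adjusted p under 0.05 and a log2 difference of at least 1. Of these, 368 were higher and 1009 lower in SG.

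Of 14 sebocyte genes measured, 11 were higher in SG than in IFE and 1 was lower, the same counts adjusted over the list alone. Cidea, a lipid droplet protein, rose by 4.61 ± 0.21, the elongase Elovl3 by 4.37 ± 0.24, and Soat1, which esterifies cholesterol, by 4.63 ± 0.34. Dgat2, a triglyceride synthesis enzyme on the list, was lower in SG by the same test (-1.92 ± 0.21, adjusted p = 0.000111). The list was higher than other genes in camera (adjusted p = 3.56e-15; adjusted p = 0.137 with an estimated correlation). Among 13 PPAR targets, 8 rose and 2 fell, counts that were equal when adjusted over the list alone (camera adjusted p = 0.000115; adjusted p = 0.169 with an estimated correlation). Pparg itself, the nuclear receptor of sebocyte differentiation, was higher by 3.38 ± 0.30 and Lpl, a lipase, by 2.94 ± 0.29, while the acyl-CoA synthetase Acsl1 was lower (-2.37 ± 0.26). Fatty acid synthesis and elongation split: 6 of 20 genes rose, with Scd3 at 3.84 and Acacb at 2.49, and 5 fell, with Scd2 at -2.05 and Elovl7 at -1.45 (adjusted p = 0.00249; adjusted p = 0.243 with an estimated correlation). The 6 and 5 were also the counts adjusted over the list alone. Peroxisomal genes showed 6 of 16 higher, among them Pex11a (1.83 ± 0.28) and catalase, Cat (1.80 ± 0.28), and 1 lower, Agps (-1.03 ± 0.29), in all genes and over the list alone (adjusted p = 0.00068; adjusted p = 0.384 with an estimated correlation). The call of Agps ended without any 1 of 4 arrays, SG replicates 1 and 2 and IFE replicates 2 and 3 (adjusted p up to 0.111), and with quantile normalization, median centring, the letter block or the brightest probe set. Wax ester, triglyceride and sterol ester enzymes rose for 4 of 12, with Awat2 at 1.46 ± 0.20, and fell for 1, Dgat2, in both counts (adjusted p = 0.00155; adjusted p = 0.243 with an estimated correlation). Lipid droplet genes rose for 3 of 13, with Plin2, the droplet coat protein, at 4.29 ± 0.32, and fell for 2, Abhd5 (-1.29 ± 0.15) and Lipe (-1.14 ± 0.24), in both counts (adjusted p = 0.0211; adjusted p = 0.217 with an estimated correlation). The list had an adjusted p of 0.0613 without SG replicate 1, and Lipe was not called without SG replicate 3 (log2 difference -0.993). Glutathione and xenobiotic genes rose for 4 of 18 and fell for none in both counts, with Mgst1 at 3.11 ± 0.39 and Gsta3 at 2.83 ± 0.45 (adjusted p = 0.00018; adjusted p = 0.279 with an estimated correlation). In cholesterol synthesis 2 of 17 genes rose, Nsdhl and Msmo1, and 1 fell, Sc5d, by all genes and over the list alone, and the list did not stand apart (adjusted p = 0.512). Nsdhl was not called without IFE replicate 1 (0.919). The steroid dehydrogenase Hsd3b6 was 4.52 ± 0.31 higher in SG.

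Genes of the infundibulum and sebaceous duct, the passage from the gland to the surface, were also higher in SG than in IFE. Their list values were higher still in HF, at 0.697 to 0.827 on the HF arrays against 0.233 to 0.62 on the SG arrays. Of 8 measured, 5 rose, also when adjusted over the list alone, with the antimicrobial peptide Defb6 at 4.29 ± 0.28 and the keratin Krt79 at 4.01 ± 0.35 (camera adjusted p = 1.88e-05; adjusted p = 0.0781 with an estimated correlation). Of 14 resting follicle genes, 7 rose and none fell, again with equal counts adjusted over the list alone, led by Fgf18 (3.14 ± 0.30), Lhx2 (1.90 ± 0.20), Tbx1 (1.57 ± 0.17) and Lgr5 (1.80 ± 0.20), transcription and growth factors and a receptor found in follicle stem cell regions. This list kept its call with an estimated correlation (adjusted p = 7.28e-09 and 0.0219). Of 16 hair shaft and inner root sheath genes, 7 were higher and 1, Hoxc13, lower, in all genes and over the list alone (adjusted p = 0.000226; adjusted p = 0.525 with an estimated correlation and 0.208 with fry). Much of the rise of this list lay in a single library: Krt27 stood at 11.5 on SG replicate 3 and at 7.90 and 8.21 on SG replicates 1 and 2, against 5.88 to 6.25 on the IFE arrays. The list values of SG replicates 1 and 2, -1.65 and -1.30, still lay above the -1.94 to -1.87 of the IFE arrays. The list was not among the camera calls that ended without SG replicate 3. Without SG replicate 3 the median difference of the hair shaft list was 0.43 instead of 1.37, with 7 genes higher and 3 lower. Hoxc13 lost its call without SG replicate 1, SG replicate 2 or IFE replicate 2 (adjusted p up to 0.0659).

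Cornified envelope genes were lower in SG than in IFE for 12 of 20 measured and higher for 1, and for 13 and 1 adjusted over the list alone (camera adjusted p = 5.13e-07; adjusted p = 0.131 with an estimated correlation). The transglutaminase Tgm3 fell by 1.94 ± 0.17 on the log2 scale, Lce1l by 3.01 ± 0.29 and the cross-linked plaque protein periplakin, Ppl, by 1.93 ± 0.21, whereas Sprr4 was higher (2.96 ± 0.26). Of 15 barrier lipid genes, 9 fell and 1 rose, with the same counts over the list alone (adjusted p = 0.000522; adjusted p = 0.295 with an estimated correlation). The lipid transporter Abca12 was lower at -3.05 ± 0.22, the lipoxygenase Aloxe3 at -2.70 ± 0.21 and the glucosylceramide synthase Ugcg at -3.30 ± 0.28, and the riser was Fa2h. In the desmosome and junction list 10 of 21 genes fell and 2 rose, as adjusted over the list alone (adjusted p = 9.46e-05; adjusted p = 0.243 with an estimated correlation). Dsc1 was at -2.09 ± 0.18 and E-cadherin, Cdh1, at -1.44 ± 0.16. Suprabasal IFE genes were lower for 7 of 12 and higher for 1, Krt77 (2.04 ± 0.28), in both counts (adjusted p = 4.44e-05; adjusted p = 0.169 with an estimated correlation). The protease Asprv1 was at -2.13 ± 0.17. Basal keratinocyte genes were lower for 2 of 9, the integrins Itga6 (-1.71 ± 0.24) and Itgb1 (-1.21 ± 0.25), also over the list alone (adjusted p = 0.0124; adjusted p = 0.336 with an estimated correlation). Leaving out the dimmer 50% of genes gave that list an adjusted p of 0.113, and Itgb1 was not called without IFE replicate 3 (log2 difference -0.973).

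Immediate early genes, which respond within minutes to handling of a tissue, were lower in SG for 11 of 15 measured, also over the list alone (adjusted p = 5.57e-07; adjusted p = 0.298 with an estimated correlation). Btg2 lay at -2.36 ± 0.20, Zfp36 at -2.44 ± 0.22, Dusp1 at -2.45 ± 0.26 and Atf3 at -2.95 ± 0.35. Of 6 heat shock genes, 2 were lower, Dnajb1 (-2.13 ± 0.27) and Hspa1a (-1.60 ± 0.20), in all genes and over the list alone (adjusted p = 0.00201; adjusted p = 0.169 with an estimated correlation). These lists moved with the IFE, beside its cornified and barrier genes. The balance of rises and falls depended on the scaling of the arrays. With quantile normalization 609 genes were higher and 476 lower in SG (56.1% higher against 26.7%), and the median difference of all genes went from -0.063 to 0.16. Using the brightest probe set of each gene turned Serpinb7 to 0.20 and ended the camera calls of the fatty acid (adjusted p = 0.0845), wax ester (0.0985) and lipid droplet (0.208) lists. It also ended the calls of 13 genes named here, Acacb, Agps, Awat2, Cidea, Fgf18, Hoxc13, Itgb1, Lce1l, Lgr5, Lipe, Lpl, Msmo1 and Nectin3. The letter block ended those of Agps, Fabp4, Itgb1 and Msmo1, quantile normalization those of Abhd5, Agps, Itgb1 and Lipe, median centring that of Agps, and array weights that of Sprr2e.

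Against the IFE, the HF was higher in 14 of 16 hair shaft and inner root sheath genes, a list that stood apart in camera but not with an estimated correlation (adjusted p = 0.22). The keratin-associated protein gene Krtap19-4 was 174-fold higher in HF (log2 difference 7.44 ± 0.48 SE, n = 3 per group, adjusted p = 5.21e-06). The fatty acid binding protein gene Fabp4 followed (7.14 ± 0.65), then the keratins Krt33a (6.98), Krt27 (6.90) and Krt25 (6.81) and the orphan receptor Gprc5d (6.52). The largest falls were in Skint9 (-4.29 ± 0.92, adjusted p = 0.00951), Serpinb7 (-4.17 ± 0.36), Sprr2d (-4.06), Tmem45a2 (-4.03), Sprr2e (-3.76) and Serpina12 (-3.47). Altogether 916 genes (6.31%) changed, 429 higher and 487 lower in HF. Sprr2e was not called without HF replicate 2 or IFE replicate 2 (adjusted p up to 0.0832).

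Hair shaft and inner root sheath genes rose for 14 of 16 measured and none fell, also over the list alone (camera adjusted p = 1.35e-19; adjusted p = 0.22 with an estimated correlation). Krt34 (5.32 ± 0.43), Krt72 (5.02 ± 0.45) and Krt83 (3.31 ± 0.32) were among them. Of 14 resting follicle genes 9 rose and none fell, over the list alone as well (adjusted p = 1.39e-14; adjusted p = 0.0151 with an estimated correlation). The list included Lgr5 (2.23 ± 0.20), Lhx2 (2.19 ± 0.20), Foxc1 (2.39 ± 0.26) and Fgf18 (2.73 ± 0.30). The infundibulum and duct list had 5 of 8 higher in both counts (adjusted p = 8.91e-10; adjusted p = 0.0219 with an estimated correlation). The kallikrein protease Klk10 was at 3.31 ± 0.29. Desquamation proteases and inhibitors were mixed, with 5 of 11 higher and 2 lower, also over the list alone (adjusted p = 0.0119; adjusted p = 0.304 with an estimated correlation). The inhibitor Spink12 (3.51 ± 0.19) and Klk6 (3.45 ± 0.40) rose, and Serpinb12 (-2.95 ± 0.38) and the caspase Casp14 (-1.94 ± 0.25) fell. In the BMP and TGF-beta list 4 of 20 genes rose and 1 fell, and 6 and 1 over the list alone (adjusted p = 8.17e-06; adjusted p = 0.169 with an estimated correlation). Bmp4 was at 2.72 ± 0.46, Fstl1 at 2.03 ± 0.18 and Inhba at 1.55 ± 0.19. Wnt ligands and targets had 5 of 24 higher and none lower in both counts (adjusted p = 0.036; adjusted p = 0.48 with an estimated correlation and 0.0773 with fry). The call ended without HF replicate 1 (0.0526), HF replicate 3 (0.0502) or IFE replicate 2 (0.0916). The genes higher included the transcription factors Lef1 (2.22 ± 0.33) and Tcf7 (1.34 ± 0.22) and the feedback inhibitor Nkd1 (1.52 ± 0.24).

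Sebocyte genes were partly raised in HF, with 7 of 14 higher than in IFE and 1 lower in both counts (adjusted p = 1.32e-05; adjusted p = 0.243 with an estimated correlation). Elovl3 was higher by 2.78 ± 0.24, Far2 by 2.52 ± 0.29 and the melanocortin receptor Mc5r by 2.17 ± 0.31. The sebocyte list was highest on HF replicate 2 among the HF arrays (0.02 against -0.48 and -0.40), which also held the highest cornified envelope values of the HF arrays (0.14 against -0.32 and -0.22). Suprabasal IFE genes were lower in HF for 5 of 12 and higher for 1, Krt77, in both counts (adjusted p = 4.44e-05; adjusted p = 0.169 with an estimated correlation), and the differentiation keratins Krt2 and Krt10 stood at -2.45 ± 0.30 and -1.32 ± 0.18. Cornified envelope genes fell for 10 of 20 and rose for 2, Sprr4 (4.00 ± 0.26) and Tgm5 (1.07 ± 0.24), in both counts (adjusted p = 0.000653; adjusted p = 0.2 with an estimated correlation). Tgm5 lost its call without HF replicate 2 (0.948), HF replicate 3 (0.972) or IFE replicate 1 (0.85). Barrier lipid genes fell for 7 of 15 and rose for 1 in both counts (adjusted p = 0.000226; adjusted p = 0.278 with an estimated correlation). Asah2, a ceramidase, was at -2.98 ± 0.26 and Alox12b at -2.39 ± 0.26. Basal keratinocyte genes fell for 2 of 9 in both counts, Itga6 (-1.94 ± 0.24) and Itgb4 (-1.03 ± 0.18; adjusted p = 0.00045 for the list, and adjusted p = 0.243 with an estimated correlation). Itgb4 was not called without HF replicate 1 (-0.989) or IFE replicate 3 (-0.859).

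In cholesterol synthesis 4 of 17 genes were lower in HF and none higher in both counts, with Sc5d at -1.48 ± 0.21 and Pmvk at -1.62 ± 0.39 (adjusted p = 0.0027; adjusted p = 0.525 with an estimated correlation). The list lay at -0.20 on IFE replicate 1, against 0.44 and 0.40 on the other IFE arrays and -0.07 on HF replicate 2, so the groups overlapped, and fry gave an adjusted p of 0.0827. Pmvk lost its call without HF replicate 1, HF replicate 3, IFE replicate 2 or IFE replicate 3 (adjusted p up to 0.0878). Of 13 PPAR targets 3 rose and 1 fell in both counts, with Cd36 at 2.41 ± 0.31 and Acsl1 at -2.12 ± 0.26 (adjusted p = 0.0252; adjusted p = 0.3 with an estimated correlation). Without HF replicate 2 the list had an adjusted p of 0.088.

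Langerhans cell genes, which mark the dendritic cells of the epidermis, were lower in HF than in IFE for 4 of 10 in both counts (adjusted p = 0.00881; adjusted p = 0.288 with an estimated correlation). H2-Aa was at -1.25 ± 0.26 and Cd207 at -1.03 ± 0.21, and Cd207 was not called without HF replicate 2 (-0.839), HF replicate 3 (-0.973) or IFE replicate 2 (-0.941). Thy1, on the epidermal T cell list, was lower by -2.38 ± 0.41, although that list of 10 genes did not stand apart (adjusted p = 0.831) with 1 gene lower in both counts. Among alarmins, Il33 (-2.80 ± 0.30) and Tslp (-2.37 ± 0.29) were lower in HF and Defb6 was higher (3.36 ± 0.28), with 3 of 20 genes higher and 4 lower, or 3 and 5 over the list alone (adjusted p = 0.669). Immediate early genes were lower for 6 of 15 and higher for 1, Egr2, in both counts (adjusted p = 0.000121; adjusted p = 0.386 with an estimated correlation). Dusp1 was at -2.18 ± 0.26 and Fos at -1.97 ± 0.30. Of 6 heat shock genes 2 were lower in both counts, Hspa1a (-1.54 ± 0.20) and Dnajb1 (-1.35 ± 0.27; adjusted p = 0.0289 for the list, and adjusted p = 0.237 with an estimated correlation). That call ended without HF replicate 2 (0.0552) or IFE replicate 1 (0.086). Cell cycle genes were lower as a list in HF (adjusted p = 0.00444; adjusted p = 0.604 with an estimated correlation), with Prc1 alone changed among 23 in both counts (-1.24 ± 0.27) and not called without IFE replicate 2 or IFE replicate 3 (adjusted p up to 0.0581). That list was at -0.17 on IFE replicate 1, against 0.45 and 0.48 on the other IFE arrays and -0.16 on HF replicate 3, and fry gave an adjusted p of 0.195. With quantile normalization 495 genes were higher and 355 lower in HF (58.2% higher against 46.8%), and the Wnt and heat shock calls ended (adjusted p = 0.0614 for each). Leaving out the dimmer 50% of genes gave 597 changed genes in place of 916 and ended the calls of the cornified envelope (0.0956), Langerhans cell (0.0956), PPAR (0.106), cell cycle (0.112) and heat shock (0.0966) lists. The brightest probe set turned Serpinb7 to 0.882, Fgf18 to -0.368, Nkd1 to -0.735 and Thy1 to 0.0608 and ended the calls of the Langerhans cell (0.219), Wnt (0.767), PPAR (0.0982) and heat shock (0.0737) lists. It also ended the calls of 14 named genes, Aldh1a3, Cd207, Dnajb1, Foxc1, Fstl1, Il33, Inhba, Krt10, Lgr5, Mc5r, Prc1, Stra6, Tcf7 and Tgm5. Quantile normalization ended those of Cd207, Itgb4 and Krt10, median centring that of Cd207, and array weights that of Tgm5. The letter block ended the calls of Skint9, Dnajb1, H2-Aa, Itgb4, Pmvk, Prc1 and Srd5a1.

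SG and HF were set against each other to separate the gland from the follicle it is attached to. SG was higher in 13 of 14 sebocyte genes and lower in 13 of 16 hair shaft and inner root sheath genes, lists that stood apart in camera but not with an estimated correlation (adjusted p = 0.131 and adjusted p = 0.243). The largest rise in SG was in Akr1c21, 8.87-fold higher (log2 difference 3.15 ± 0.43 SE, n = 3 per group, adjusted p = 0.00104). Next came the elongase Elovl6 (3.02 ± 0.44), the cell surface protein Emb (2.98), the cytochrome P450 gene Cyp2g1 (2.97), the deacetylase Aadac (2.93) and the acyl-CoA oxidase-like gene Acoxl (2.88). HF was higher in Fabp4 (-5.01 ± 0.65, adjusted p = 0.000821), Krtap19-4 (-4.80), Gprc5d (-4.59), the carbonic anhydrase Car6 (-4.57 ± 0.29), Krtap13-1 (-4.43) and Krt34 (-4.33). There were 741 changed genes (5.11%), 262 higher and 479 lower in SG.

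Sebocyte genes were higher in SG than in HF for 13 of 14 measured and none was lower, in both counts (camera adjusted p = 2.17e-16; adjusted p = 0.131 with an estimated correlation). Cidea was at 2.68 ± 0.21, Far2 at 2.82 ± 0.29 and Pparg at 2.60 ± 0.30. Cholesterol synthesis genes were higher for 4 of 17, and for 6 over the list alone, with none lower (adjusted p = 0.000129; adjusted p = 0.414 with an estimated correlation and 0.0851 with fry). Hmgcs1, which makes the first committed precursor, was higher by 1.13 ± 0.20 and Msmo1 by 1.60 ± 0.30. Peroxisomal genes were higher for 6 of 16 and lower for 1, Crot, in both counts (adjusted p = 7.85e-05; adjusted p = 0.306 with an estimated correlation). Scp2 was at 1.73 ± 0.25. Wax ester, triglyceride and sterol ester enzymes were higher for 5 of 12 and lower for none in both counts (adjusted p = 0.00123; adjusted p = 0.243 with an estimated correlation). They included Awat2 (1.18 ± 0.20) and Dgat1 (1.46 ± 0.29). Fatty acid genes were higher for 7 of 20, with Scd1 at 1.55 ± 0.21, and lower for 2, the desaturases Fads3 (-2.30 ± 0.24) and Scd2 (-1.25 ± 0.31), in both counts (adjusted p = 0.0114; adjusted p = 0.295 with an estimated correlation). Quantile normalization gave that list an adjusted p of 0.0614, and Scd2 lost its call without any 1 of 5 arrays (adjusted p up to 0.0947), SG replicates 1 and 2 and the 3 HF arrays. Genes of androgen, steroid and retinoid metabolism did not stand apart (adjusted p = 0.876), with 1 of 17 higher and 1 lower in both counts, a mean of 0.03 and a median of -0.36. Lipid droplet genes were higher for 2 of 13, Plin2 (2.67 ± 0.32) and Cidea, and lower for 1, Lipe (-1.28 ± 0.24), in both counts (adjusted p = 0.00369; adjusted p = 0.169 with an estimated correlation). PPAR targets were higher for 6 of 13, with Lpl at 2.11 ± 0.29, and lower for 1, Fabp4, in both counts (adjusted p = 0.00511; adjusted p = 0.243 with an estimated correlation). Glutathione and xenobiotic genes were higher for 4 of 18, or 5 over the list alone, and lower for none (adjusted p = 0.000763; adjusted p = 0.3 with an estimated correlation and 0.0641 with fry). Mgst1 was at 2.50 ± 0.39 and Gsta4 at 1.97 ± 0.33. Langerhans cell genes were higher in SG for 4 of 10 in both counts (adjusted p = 1.32e-05; adjusted p = 0.169 with an estimated correlation). H2-Aa was at 1.76 ± 0.26 and the invariant chain, Cd74, at 1.28 ± 0.27. Cd74 was not called without SG replicate 2 or HF replicate 1 (adjusted p up to 0.0555).

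Hair shaft and inner root sheath genes were lower in SG than in HF for 13 of 16, and for 15 over the list alone, with none higher (adjusted p = 3.83e-14; adjusted p = 0.243 with an estimated correlation). SG replicate 3 narrowed the difference, at 1.18 on this list against -1.65 and -1.30 on SG replicates 1 and 2. Desmosome and junction genes were lower for 6 of 21 and higher for none in both counts (adjusted p = 3.25e-10; adjusted p = 0.169 with an estimated correlation). The desmocollin Dsc2 was at -2.44 ± 0.27 and the connexins Gjb2 (-2.16 ± 0.31) and Gja1 (-1.75 ± 0.27). Desquamation genes were lower for 6 of 11 and higher for none in both counts (adjusted p = 0.000169; adjusted p = 0.227 with an estimated correlation). Members included the proteases Tmprss11e (-1.71 ± 0.20), Klk7 (-1.82 ± 0.29) and St14 (-1.64 ± 0.30). Cornified envelope genes were lower in SG than in HF for 5 of 20 and higher for none in both counts, with Ppl at -1.30 ± 0.21 and Crct1 at -1.28 ± 0.20 (adjusted p = 0.00255; adjusted p = 0.237 with an estimated correlation). Immediate early genes were lower for 2 of 15 in both counts, Ppp1r15a (-1.58 ± 0.22) and Btg2 (-1.13 ± 0.20; adjusted p = 0.00207 for the list, and adjusted p = 0.52 with an estimated correlation and 0.101 with fry). In the BMP and TGF-beta list 3 of 20 genes were lower and 1 was higher in both counts, with Bmp4 at -3.34 ± 0.46 and Smad7 at -1.18 ± 0.19 (adjusted p = 0.00155; adjusted p = 0.243 with an estimated correlation). The resting follicle list did not stand apart between SG and HF in camera (adjusted p = 0.174), although it was lower in SG with fry (adjusted p = 0.00473). Of its 14 genes 2 were lower in SG in both counts, Krt75 (-1.62 ± 0.30) and Krt17 (-1.11 ± 0.28). Krt17 lost its call without any 1 of 4 arrays (adjusted p up to 0.0963), SG replicates 1 and 2 and HF replicates 2 and 3. The infundibulum and duct list did not stand apart in camera either (adjusted p = 0.253), and was lower in SG with fry (adjusted p = 0.0383). Of its 8 genes 1 was lower in SG, or 2 over the list alone, and none higher. Cell cycle genes as a list were higher in SG (adjusted p = 0.0333; adjusted p = 0.699 with an estimated correlation and 0.509 with fry) with no member changed in either count, and the value of the list was 0.55 on SG replicate 3 against -0.42 and -0.17 on the other SG arrays. Without SG replicate 3 the median difference of that list turned from 0.22 to -0.05 and its adjusted p was 0.833, and without HF replicate 2 it was 0.0816. With quantile normalization 403 genes were higher and 402 lower in SG (50.1% higher against 35.4%), and the brightest probe set turned Acoxl to -0.504, Awat2 to -0.114 and Dsc2 to 0.00192 and ended the calls of the fatty acid (0.0524), wax ester (0.202), lipid droplet (0.176), PPAR (0.377), BMP (0.288) and cell cycle (0.218) lists. It also ended the calls of 13 named genes, Btg2, Cd74, Cidea, Crct1, Cyp2g1, Fads3, Gja1, Klk7, Krt17, Lipe, Lpl, Scd1 and Tgfa. Leaving out the dimmer 50% of genes took the PPAR list to 0.334. The letter block ended the calls of Awat2, Cd74, Crct1, Dgat1, Gsta4, Hmgcs1, Krt17, Mgst1, Msmo1, Ppl, Scd2, St14 and Tgfa.

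A signature was taken as the genes higher in a compartment than in each of the others, at the same threshold in both comparisons. The SG signature held 142 genes, the HF signature 188 and the IFE signature 336. The SG signature was led by Akr1c21, whose smaller difference was 3.15, and by Elovl6, Emb, Cyp2g1, Acoxl, Soat1 (2.87), Far2 (2.82) and Cd36 (2.76). With the brightest probe set Acoxl turned to -0.504 in SG against HF and Cyp2g1 lost its call there, so neither would stay in that signature. The HF signature was led by Fabp4 (5.01), which is also on the adipocyte list, Krtap19-4, Gprc5d, Car6, Krt34, Krt33a, Krt31 (4.24) and Krt72 (4.06). The difference of Krt31 from SG was narrowed by SG replicate 3, where it stood at 10.3 against 7.051 and 6.555 on SG replicates 1 and 2. The IFE signature was led by Serpinb7 (3.51), Lce1d (3.44), Sprr2e (3.43), Il1f9 (3.42), Ly6m (3.37), Wfdc12, Tmem45a2 and Serpina12 (3.26). The first rank of Serpinb7 did not hold with the brightest probe set, which put it at 0.202 in SG against IFE (adjusted p = 0.394) and at 0.882 in HF against IFE (adjusted p = 0.00401), the opposite direction. Sprr2e was uneven among the IFE arrays, at 9.30 ± 2.3 (SD, n = 3), and in SG against IFE it was not called without SG replicate 2, IFE replicate 1 or IFE replicate 2 (adjusted p up to 0.0807). Keratins, keratin-associated proteins, small proline-rich and late cornified envelope genes belong to families of near-identical copies that can share probe signal, so single members are uncertain. Krt84, a keratin of the tail scale named after its values were seen, was highest in IFE at 13.96 ± 0.14, against 11.36 ± 0.66 in SG and 11.89 ± 0.50 in HF (SD, n = 3), with log2 differences of -2.60 and -2.07. Krt31, its companion on the scale list, followed the hair keratins instead, at 12.2 in HF and 6.17 in IFE.

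**Figure D3:**
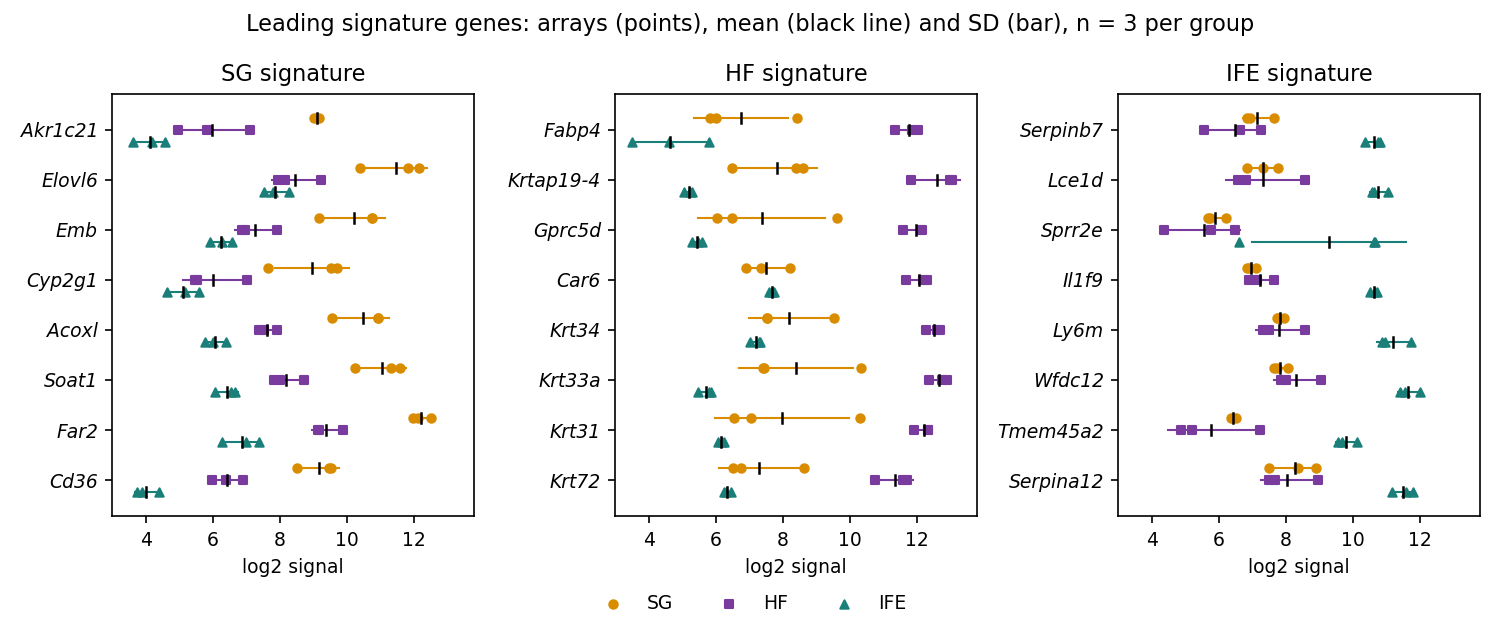
Log2 signal of the 8 leading genes of each signature on every array (points), with group means (black lines) and SDs (bars), n = 3 per group, SG as circles, HF as squares and IFE as triangles. Akr1c21 is at 9.11 in SG against 5.97 in HF, Fabp4 at 11.76 in HF against 6.75 in SG, and Il1f9 at 10.64 in IFE against 7.22 in HF.

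With quantile normalization the SG signature held 230 genes, the HF signature 190 and the IFE signature 220. Leaving out the dimmer 50% of genes gave 91, 119 and 259, and the letter block 88, 129 and 202. With SG replicate 3 and HF replicate 2 both left out, chosen after the data were seen, the signatures held 174, 243 and 389 genes for SG, HF and IFE. The pairwise counts were then 1703 for SG against IFE, 1069 for HF against IFE and 1047 for SG against HF.

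Markers of other cell types that a dissected piece could carry were set beside these gene groups. Fibroblast genes were higher as a list in SG than in IFE (camera adjusted p = 0.0286; adjusted p = 0.269 with an estimated correlation), with no gene of 9 changed in either count, and the decorin gene Dcn stood at 8.33 ± 1.1 in SG and 7.29 ± 0.53 in IFE (SD, n = 3). The fibroblast call ended with the brightest probe set (0.136), without the dimmer 50% of genes (0.0835) and without IFE replicate 2 (0.0619). Melanocyte genes were higher as a list in SG than in IFE (adjusted p = 0.00511; adjusted p = 0.298 with an estimated correlation), with Pmel changed among 10 in both counts (1.30 ± 0.37) and with the highest list value, 0.58, on SG replicate 3. SG replicate 1, at -0.14, lay below IFE replicate 3, at -0.04. Neither the melanocyte nor the fibroblast list passed in HF against IFE (adjusted p = 0.0568 and adjusted p = 0.08). Pmel lost its call without SG replicate 2, SG replicate 3, IFE replicate 1 or IFE replicate 2 (adjusted p up to 0.0939). The adipocyte list was higher in SG than in IFE (adjusted p = 0.0348; adjusted p = 0.237 with an estimated correlation) with Fabp4 changed among 8 genes in both counts. In HF against IFE its mean was larger, 1.01 against 0.49, with a median of 0.15 and Fabp4 again the gene changed. There it did not pass in camera (adjusted p = 0.0512) but did with fry (adjusted p = 0.00359). The adipocyte values were 0.40 to 0.58 on the HF arrays and -0.17 to 0.23 on the SG arrays, and SG against HF did not pass (adjusted p = 0.849). The call in SG against IFE ended with the brightest probe set (0.0866), quantile normalization (0.0691), and without SG replicate 1 (0.0616), IFE replicate 2 (0.0619) or IFE replicate 3 (0.0564). Fabp4 lost its own call without SG replicate 3, IFE replicate 2 or IFE replicate 3 (adjusted p up to 0.139), with the letter block, and with eBayes with trend and robust. Endothelial genes did not stand apart in camera in SG against IFE (adjusted p = 0.0574), HF against IFE (adjusted p = 0.0746) or SG against HF (adjusted p = 0.746), and 0 of 9 changed in limma, while 2, 1 and 0 of them had an adjusted p under 0.05. With fry that list passed in SG against IFE alone (adjusted p = 0.0476). Muscle, dermal papilla and Merkel cell lists did not stand apart in any comparison in camera. With fry the muscle list passed in HF against IFE (adjusted p = 0.00967) and in SG against HF (adjusted p = 0.0243). Acta2, of smooth muscle, was higher in HF than in IFE (1.96 ± 0.19, adjusted p = 6.68e-05). Of 114 pairs of list and comparison, 56 passed an adjusted p of 0.05 with camera's preset correlation. With an estimated correlation 3 passed, the resting follicle list in SG and in HF against IFE, and the infundibulum and duct list in HF against IFE. The tail scale (2 genes measured), Schwann cell (2) and blood (1) lists were too small to test.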

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

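The fit without SG replicate 3 and HF replicate 2 together was chosen after the data were seen, and gave 3536 genes differing among the compartments. Counts of changed genes stayed within 1.5 times under median centring, the milder filter on dim genes, the brightest probe set, eBayes with trend and robust, and a fit of only the groups compared. The brightest probe set shared only 808 of 1377 calls with the same direction in SG against IFE (3 opposite), 521 of 916 in HF against IFE (1 opposite) and 431 of 741 in SG against HF (1 opposite). The cause was not tested for the movements below except where fewer genes were tested, and the letter block changes the design. Under it SG replicate 1, HF replicate 1 and IFE replicate 3, which shared a letter with no other array, did not inform the comparisons. Fewer calls follow from that loss of arrays, so its counts are no sign of a batch. The letter block gave 1360 genes differing among the compartments, 392 for SG against HF, and signatures of 88 (SG) and 202 (IFE) genes. Array weights gave 5890 genes differing. Quantile normalization gave signatures of 230 (SG) and 220 (IFE). The stricter filter on dim genes, which tests fewer genes, gave 597 for HF against IFE and signatures of 91 (SG) and 119 (HF). Log2 thresholds of 0 and 2 gave 3171 and 226 genes for SG against IFE, 1750 and 214 for HF against IFE, 1373 and 137 for SG against HF, and signatures of 248 and 39 (SG), 300 and 62 (HF), and 791 and 53 (IFE).

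Leaving out single arrays gave 2305 (without IFE replicate 2) to 4436 (without IFE replicate 1) genes differing among the compartments, 1146 to 1752 for SG against IFE, 763 to 1146 for HF against IFE, and 535 to 994 for SG against HF. The label check difference of the resting hair follicle list ran from 0.733 to 0.985, and its exact permutation p rose to 0.143 without an HF array and 0.125 without an IFE array, and to 0.0357 without an SG array. With an estimated correlation 3 of 56 list calls passed. fry called 58 pairs, including 47 of the 56, the brightest probe set 42, including 39, and quantile normalization 51.

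Same-numbered arrays were left unpaired in the main fit. The correlation of their deviations exceeded 0.1 in 2 of 9 pairs (-0.019 to 0.23) and was below 0 only for SG replicate 2 with IFE replicate 2. Of the 9 arrays, 5 correlated best with their own number. These values do not settle whether same-numbered samples share an origin. With the replicate block 3990 genes differed among the compartments, against 3548 without it. In the comparisons 1398, 944 and 781 changed, against 1377, 916 and 741. The block ended 1 list call, androgen, steroid and retinoid genes in SG against IFE (adjusted p = 0.0549).

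Of 199 results of single genes named in the text, 60 lost their call under at least 1 alternative without changing sign. Another 8 results changed sign under 1 alternative and were not called there either, and Awat2 in SG against HF is in both counts. Of the 8, only Serpinb7 in HF against IFE had an adjusted p under 0.05 in limma after the change. The others had 0.0592 to 0.997, so for them the call was lost and an opposite change was not shown. The brightest probe set weakened 40 of the 199 and made all 8 reversals, the letter block weakened 24 and the replicate block 0. The brightest probe set took Serpinb7 to 0.202 in SG against IFE and 0.882 in HF against IFE (adjusted p = 0.00401). In HF against IFE it took Fgf18 to -0.368, Nkd1 to -0.735 and Thy1 to 0.0608. In SG against HF it took Acoxl to -0.504, Awat2 to -0.114 and Dsc2 to 0.00192. It rests on a single probe set per gene, and the cause was not tested. Without detection calls, changes in dim genes are limited by their unknown signal over background.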

Other observations

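The tests on SG replicate 3, HF replicate 2 and the cell cycle genes were chosen only after the values they measure had been seen, and the explanations for HF replicate 2 were reworked after its first values. Genes of androgen, steroid and retinoid metabolism were higher as a list in SG than in IFE (camera adjusted p = 0.0383; adjusted p = 0.371 with an estimated correlation). In limma 2 of 17 rose, Hsd3b6 and the dehydrogenase Hsd17b2 (1.85 ± 0.26), and 1 fell, the retinol dehydrogenase Dhrs9 (-2.28 ± 0.24), counts that were equal adjusted over the list alone. The list call ended with the brightest probe set (0.333), quantile normalization (0.103), the filter on the dimmer genes (0.0766), and without SG replicate 3 (0.07) or IFE replicate 3 (0.0537). In HF against IFE 4 rose, among them the retinoic acid synthesis enzyme Aldh1a3 (1.56 ± 0.25) and the retinol transporter Stra6 (1.49 ± 0.17), and 2 fell, Dhrs9 (-1.82 ± 0.24) and Srd5a1 (-1.15 ± 0.23), in both counts (adjusted p = 0.0137; adjusted p = 0.3 with an estimated correlation and 0.0637 with fry). This call ended with the brightest probe set (0.139) and the filter on the dimmer genes (0.0556), and Srd5a1 was not called without HF replicate 1 (log2 difference -0.98). Receptors and ligands of the EGFR and FGF families were lower as a list in SG than in HF (adjusted p = 0.0136; adjusted p = 0.169 with an estimated correlation), with Tgfa alone changed among 19 in both counts (-1.50 ± 0.24). The call ended without SG replicate 3 (0.0575) and with the filter on the dimmer genes (0.0874).

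Genes sharing a symbol stem were also tested, over 260 families of at least 8 measured genes and 780 pairs of family and comparison, of which 38 passed and 0 passed with an estimated correlation (adjusted p = 0.995 for those 38). Keratin-associated proteins were higher in HF than in IFE for 7 of 10 and lower for 1 (camera adjusted p = 2.13e-06), and keratins were higher for 20 of 39 and lower for 3 (adjusted p = 9.7e-12). Small proline-rich genes were lower in HF for 7 of 11 and higher for 1 (adjusted p = 0.0138). Aldo-keto reductases were higher in SG than in HF for 6 of 12 and lower for none (adjusted p = 3.94e-06). Olfactory receptors, 452 genes, had a median of 0.258 in SG against IFE with 17 higher (adjusted p = 8.4e-07) and of 0.212 in SG against HF with 7 higher (adjusted p = 0.000215). In the same fit the median of all genes was -0.063 and -0.017 in these comparisons. Quantile normalization put the median of all genes at 0.16 and 0.12, and the olfactory receptors were not tested under it. Of 7772 probe sets without a single symbol, 13.3% changed in SG against IFE, 5.56% in HF against IFE and 5.56% in SG against HF, against 15.5%, 6.83% and 5.79% of the named ones.

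The array file names carry another compartment than the titles for 9 arrays. If the groups are named wrongly in the titles and rightly in the array file names, the 3 marker lists should be highest in the arrays the file names give, and 0 of 3 were. If the groups are named rightly in the titles and wrongly in the array file names, they should be highest in the titled arrays, and 3 of 3 were. The lists speak for the titles, the resting hair follicle list least, as it did not stand apart between SG and HF in camera (adjusted p = 0.174). How the file names arose stays open.

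Hair shaft transcripts in SG replicate 3 lay far above those of SG replicates 1 and 2. Hair follicle tissue in the sample of SG replicate 3 is a candidate explanation. Of 232 HF signature genes found without that array, 85.8% lay above both other SG arrays, against 47.5% of other genes. The share was 84.7% for the 203 outside the keratin families. The 232 genes were chosen for low values on SG replicates 1 and 2 and the other genes were not. A left-out array would therefore lie above both more often for the 232 in any case. An equal shift of all genes on that array is argued against by a median difference of 0.126 over the other genes, beside 0.823 for the signature genes. A narrower range of values on SG replicate 3 was not tested. Cell cycle transcripts in SG replicate 3 need another account than follicle tissue like that of the HF arrays, since 22 of 23 genes were higher there than in every other SG and HF array. That level was not particular to SG replicate 3: its list value of 0.55 lay near the 0.45 and 0.48 of IFE replicates 2 and 3, with IFE replicate 1 at -0.17. Whether the cell cycle values come from the dissected pieces or the mice stays open, and no biological explanation was tested.

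SG and IFE signature genes were highest in HF replicate 2 among the HF arrays for 81% and 78% of genes, against 42.7% of other genes. Tissue of both other compartments in that sample is a candidate explanation, but the 81% is the pattern itself and no test of it. Of HF signature genes, 68.6% were lowest on HF replicate 2 among the HF arrays, which a narrower range of values would give too. Sebaceous gland tissue alone would leave the IFE signature near the other genes, not at 78%. A narrower range of values on that array would raise dim genes too, and the dimmest genes outside those signatures differed by 0.039, beside 0.443 and 0.423 for the signatures. Such dim genes may lie near the background on every array, so this does not exclude a narrower range. The signatures were defined with HF replicate 2 among the arrays, and the amount of other tissue was not measured.

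The compartments were set against 100 splits of the 9 arrays into 3 groups of 3, the real one included. No other split gave as many genes differing among the compartments (3548 genes, highest other split 1083) or changed in SG against IFE (1377 and 581). Under the compartment names drawn for each split, the same held for SG against HF (741 and 736), the SG signature (142 and 115) and the IFE signature (336 and 316). Each other split was counted under 1 arbitrary assignment of those names to its groups. Under other names, splits among the 100 reached 998 changed genes in a pair, over 741, and signatures of 315 and 316, over 142. The results for SG against HF and the SG signature therefore rest on the names drawn. The margin was narrow for SG against HF and the IFE signature. For HF against IFE 2 of 100 splits were as large (916 and 998), and for the HF signature 4 were (188 and 315), the real split included. These shares depend on the names drawn too, and were not adjusted for the number of counts. The split with 998 genes set the 3 IFE arrays against SG replicates 1 and 2 with HF replicate 1, and the one with 315 counted genes higher in the 3 IFE arrays than in groups mixed of SG and HF arrays, so both kept the IFE arrays together. The highest other splits of the remaining counts also kept the 3 SG or the 3 IFE arrays together. They therefore held real differences and do not measure chance alone.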
